A study of Homo sapiens with 8 samples.

How the data were processed

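Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in LNCaP cells, an androgen-responsive human prostate cancer line. Per the labels' protocols, 50k cells per sample were used and libraries were made by the Omni-ATAC method. The 8 samples formed 4 groups of 2 biological duplicates: control-guide (sgCtrl) and CHD1-targeted (sgCHD1) cells, each given ethanol vehicle or 10 nM dihydrotestosterone (DHT) for 4 h after 72 h without androgen. Groups were taken from the sample titles. The treatment field names DHT for all 8 samples, the 4 titled as vehicle included, and this conflict in the labels was left as it stands.

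The deposited lists held 1 set of peaks per group, with the duplicates merged by the authors; whether reads or peak calls were merged is not given in the sources used here. Per the submitters' processing notes, MACS2 and the human build hg19 were used, without a version or a calling threshold. Each deposited list gave a chromosome, a start and an end per peak and no height, score or p, so sequencing depth and signal per peak are unknown here. Starts, which the files count from 0, are printed counting from 1. The lists were checked against the last gene of each chromosome in a GRCh38 gene table: on chromosome 9, for example, 262 peaks lay beyond it, which is compatible with a build other than GRCh38. No coordinate was converted between builds.

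Peaks were compared with bedtools 2.31.1, and tables were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9. In each of the 4 comparisons, a gained peak was a peak of the first list without a peak of the second overlapping it by at least 1 bp, and a lost peak was the reverse. Shares carry 95% Wilson intervals, which cover counting error only and treat peaks as independent. With 1 merged list per group there was no spread between replicates, so no p-value between groups was computed. Peaks of all lists that overlapped were joined into merged regions, each described by which lists held it. Widths of shared peaks were compared over peaks that matched 1 to 1. An area under the curve gave the chance that a shared peak of a list was wider than an exclusive peak of the same list.

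Shares of each list's peaks were also counted per chromosome and per 10 Mb window, over windows with at least 10 peaks in every list. Intervals of width differences came from 1000 bootstrap draws. Regions separated by at most 12.5 kb were chained into clusters, and a cluster with at least 10 regions was called dense. Runs of 10 adjoining windows were also chosen by their mean in one treatment and read in the other. The windows, runs, clusters and width comparisons were chosen after the data were seen.

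The rule written before the data were examined named the 5 gained and 5 lost peaks of highest score per comparison. Because the lists gave no score, the 5 widest of each kind were taken instead, leaving out chromosomes Y and M; where the text gives fewer, it says in which lists the others were open. Also planned were promoter shares, gene lists, motif shares and values at CHD1 and at known androgen-responsive genes. These need a genome or annotation of hg19, which was not used here, so they were not analysed here and peaks are given by position without gene names. The overlap expected of independent lists was planned for the DHT-gained regions. It was computed and set aside, because the regions it is counted over include only those found in at least 1 DHT list.

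Alternatives written before the data were examined were a 50% reciprocal overlap, lists widened by 250 bp on each side, chromosomes 1 to 22 and X alone, and peaks closer than 250 bp merged, the last 2 for the number of peaks per list. Alternatives added after seeing the data were chromosomes 1 to 22 and X for the other counts, widened lists for the DHT-gained regions shared by both genotypes, an equal number of the widest peaks from each list, a common minimum width of 114 bp, leaving out dense clusters with chromosomes Y and M, and, for the chromosome segments, counting peaks of a list within 12.5 kb of each other once. A count was taken as moved when it changed by more than 1.5 times, and a segment ratio when it left its 95% counting interval. The overlap step was tested on 790 simulated peaks, of which 0 differed from a pairwise count. The segment step was tested on 20 simulated pairs of lists made with a share ratio of 1.17, and its median was 1.16.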

Results

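Open chromatin was mapped in 4 groups of LNCaP cells: control-guide (sgCtrl) and CHD1-targeted (sgCHD1) cells under vehicle or DHT, the androgen that binds and activates the androgen receptor. CHD1 is a chromatin remodelling enzyme, and the title of the series places it as a prostate tumour suppressor that acts on nuclear receptor targeting. The design therefore asks where DHT changes accessibility, and whether those places differ once CHD1 is lost. Each group had 2 biological duplicates, merged by the authors into 1 peak list. No difference below thus has a replicate check, and depth is unknown. Vehicle and DHT lists are told apart by the sample titles alone, since the treatment field names DHT for every sample; a swap within either genotype would turn the direction of its DHT comparison. Open and closed below mean with and without a called peak in a list. A missing peak may be a site that was open but not detected. Positions are on hg19.

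The sgCtrl vehicle list held 50260 peaks covering 10.3 Mb and the sgCtrl DHT list held 20519 peaks covering 3.92 Mb. The sgCHD1 vehicle list held 31734 peaks covering 7.28 Mb and the sgCHD1 DHT list held 65463 peaks covering 15.7 Mb. Median peak widths, in the same order, were 180, 167, 200 and 207 bp. The narrowest peaks were 95, 96, 114 and 94 bp wide. The sgCHD1 vehicle list thus had a higher width floor than the others, which limits the width comparisons below that involve it.

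Joined across lists, the peaks formed 81569 regions. Of these, 12625 (15.5%) were open in all 4 lists and 35988 (44.1%) in 1 list. The most frequent combination was sgCHD1 DHT alone, with 21550 regions of median width 159 bp. Another 11096 regions were shared by sgCtrl vehicle and sgCHD1 DHT, and 10746 by every list except sgCtrl DHT. Regions open in all 4 lists had a median width of 362 bp.

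**Figure D1:**
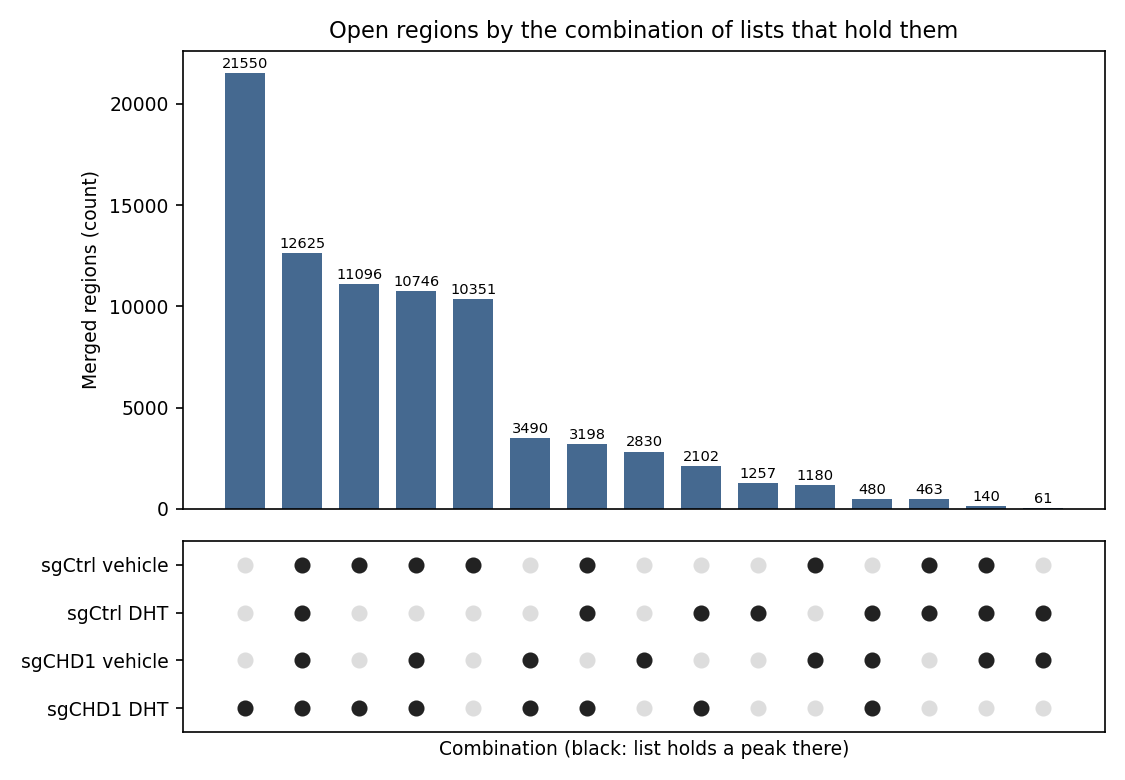
Number of merged regions (vertical axis, count) for each combination of the 4 lists; black dots mark the lists that hold a peak in the region. Regions found in sgCHD1 DHT alone (21550) outnumber the 12625 found in all 4 lists, and 61 regions were shared by sgCtrl DHT and sgCHD1 vehicle alone.

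In sgCtrl cells, the DHT list was 2.45-fold shorter than the vehicle list. DHT-gained peaks numbered 4024, or 19.6% of the DHT list (95% interval 19.1 to 20.2), and lost peaks 33822, or 67.3% of the vehicle list (66.9 to 67.7). The widest gained peaks lay at chr17:78042192-78042707 (516 bp), chr3:111853444-111853935 (492 bp) and chr4:13333306-13333787 (482 bp), and each of these was also open in sgCHD1 cells under DHT and in neither vehicle list. Of the 5 widest, chr3:23634509-23634962 (454 bp) differed in being open in both sgCHD1 lists. The widest lost peaks lay at chr9:38046767-38047502 (736 bp), chr11:61256008-61256728 (721 bp) and chr6:18465637-18466351 (715 bp), and all 5 of the widest were open in both sgCHD1 lists. Of the gained peaks, 66.9% overlapped the sgCHD1 DHT list (65.5 to 68.4) and 14.5% the shorter sgCHD1 vehicle list (13.4 to 15.6), against 96.2% and 77.4% of the DHT peaks shared with sgCtrl vehicle. Of the lost peaks, 65.8% overlapped the sgCHD1 DHT list (65.3 to 66.3) and 35.7% the sgCHD1 vehicle list (35.2 to 36.2). Of the vehicle peaks shared with sgCtrl DHT, 96.3% and 77.5% did.

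Shared peaks were also narrower in sgCtrl cells under DHT: over 16265 matched peaks the median width ratio of DHT to vehicle was 0.767, and 20.5% were wider under DHT (19.9 to 21.1). Lost peaks had a median width of 155 bp, against 250 bp for vehicle peaks that the DHT list shared, and gained peaks 132 bp, against 178 bp for shared DHT peaks. A 50% reciprocal overlap raised the gained count to 7593.

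In sgCHD1 cells, the DHT list was 2.06-fold longer than the vehicle list. DHT-gained peaks numbered 38031, or 58.1% of the DHT list (57.7 to 58.5), and lost peaks 4251, or 13.4% of the vehicle list (13.0 to 13.8). The widest gained peak, at chr10:43277804-43278779 (976 bp), was open in no other list. The next, at chr6:31619767-31620724 (958 bp), was also open in sgCtrl vehicle, and those at chr11:126173713-126174628 (916 bp) and chr1:147735399-147736283 (885 bp) were open in both sgCtrl lists. The last of the 5 widest, at chr8:1806863-1807711 (849 bp), was also open in sgCtrl vehicle. The widest lost peak, at chr21:10836200-10836692 (493 bp), was also open in sgCtrl DHT and lay near a dense cluster, chr21:10765839-10815937. The next, at chr13:25085362-25085847 (486 bp), was open in sgCHD1 vehicle alone. Those that followed, chr7:105290444-105290881 (438 bp), chr7:147935769-147936200 (432 bp) and chr12:95843388-95843798 (411 bp), were open in both vehicle lists and in neither DHT list. Of all lost peaks, 31.9% overlapped the sgCtrl vehicle list (30.6 to 33.4) and 4.75% the sgCtrl DHT list (4.15 to 5.43). Of the sgCHD1 vehicle peaks shared with sgCHD1 DHT, 84.9% and 47.4% did. Of all DHT-gained peaks in sgCHD1 cells, 37.8% overlapped the sgCtrl vehicle list (37.3 to 38.3) and 14.0% the sgCtrl DHT list (13.6 to 14.3); of the DHT peaks shared with sgCHD1 vehicle, 85.3% and 47.8% did.

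Shared peaks were wider under DHT in these cells, with a median width ratio of 1.21 over 27060 matched peaks and 73.8% wider (73.3 to 74.3). Gained peaks had a median width of 173 bp, against 273 bp for the DHT peaks that the vehicle list shared, and lost peaks 148 bp, against 211 bp for shared vehicle peaks. With a 50% reciprocal overlap the lost count was 8712.

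**Figure D2:**
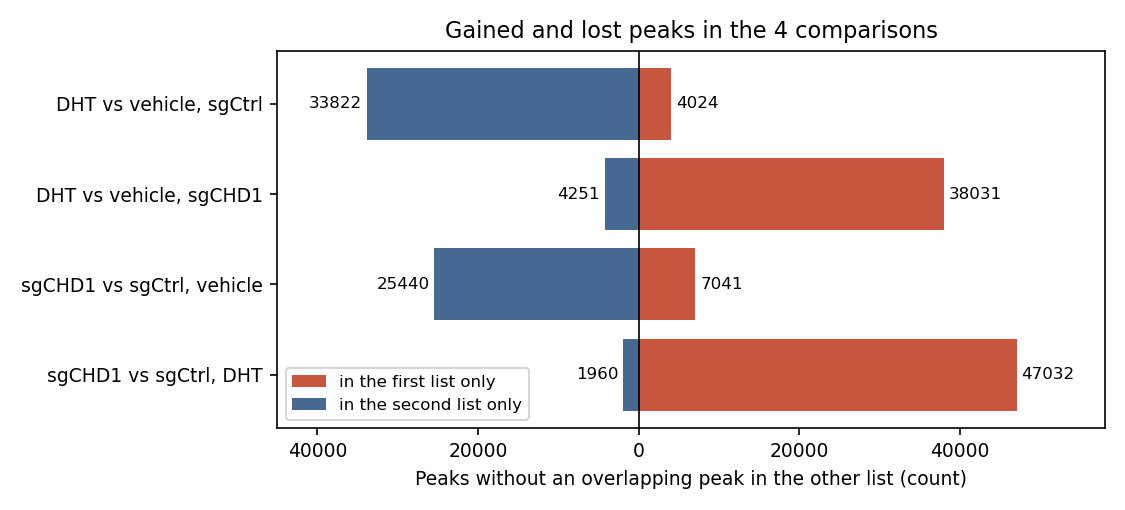
Peaks without an overlapping peak in the other list (horizontal axis, count), to the right of 0 for the first-named condition and to the left for the second. Under DHT, sgCtrl cells had 4024 gained and 33822 lost peaks, and sgCHD1 cells 38031 gained and 4251 lost.

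Under vehicle, where sgCHD1 and sgCtrl cells were compared without added androgen, the sgCHD1 list was 1.58-fold shorter than the sgCtrl list. Peaks gained in sgCHD1 cells numbered 7041, or 22.2% of their list (21.7 to 22.6), and lost peaks 25440, or 50.6% of the sgCtrl list (50.2 to 51.1). The widest gained peaks, at chr19:3185224-3185888 (665 bp) and chr2:241172590-241173247 (658 bp), were open in both sgCHD1 lists and in neither sgCtrl list, as was chr10:52499823-52500406 (584 bp). The other 2 of the 5 widest, at chr3:49142001-49142596 (596 bp) and chr2:32390328-32390904 (577 bp), were also open in sgCtrl DHT, as were 7.77% of all gained peaks (7.17 to 8.42). The widest lost peaks, at chr11:126173883-126174611 (729 bp), chr13:95201777-95202460 (684 bp) and chr1:199870452-199871120 (669 bp), were open in both sgCtrl lists but also in sgCHD1 cells under DHT. Those at chr14:22025392-22026040 (649 bp) and chr6:76328809-76329438 (630 bp) were open in sgCtrl vehicle and sgCHD1 DHT. The sgCHD1 DHT list held 57.5% of the lost peaks (56.9 to 58.1) and a similar 58.9% of the gained peaks (57.8 to 60.1), against 94.5% of the shared peaks of either list. Widths of shared peaks were close, with a median ratio of 0.968 over 24367 matched peaks and 44.7% wider in sgCHD1 cells (44.1 to 45.3).

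Under DHT, the sgCHD1 list was 3.19-fold longer than the sgCtrl list. Gained peaks numbered 47032, or 71.8% of the sgCHD1 list (71.5 to 72.2), and lost peaks 1960, or 9.55% of the sgCtrl list (9.16 to 9.96). The widest gained peaks lay at chr19:35738524-35739804 (1281 bp), chrX:149107645-149108923 (1279 bp) and chr10:131908718-131909822 (1105 bp), and all 5 of the widest were open in both vehicle lists. Of all gained peaks, 46.6% were open in sgCtrl vehicle (46.2 to 47.1) and 30.4% in sgCHD1 vehicle (30.0 to 30.8), against 85.9% and 71.2% of the sgCHD1 DHT peaks shared with sgCtrl DHT. The widest lost peaks were chr10:42796958-42797322 (365 bp), open in both sgCtrl lists, and chr11:40350702-40351047 (346 bp), open in every list except sgCHD1 DHT, as was chr12:34834041-34834375 (335 bp). The other 2 of the 5, at chr21:11141918-11142253 (336 bp) and chr4:49101709-49102034 (326 bp), were open in sgCtrl DHT alone. The latter lay in a dense cluster, chr4:49093307-49163942, with 20 open regions in sgCtrl vehicle, 20 in sgCtrl DHT, 14 in sgCHD1 vehicle and 20 in sgCHD1 DHT. The peaks on chromosomes 10 and 21 lay near the dense clusters chr10:42355976-42409396 and chr21:10765839-10815937, named below as near centromeres. No peak was left out of the rankings for such a position, so these peaks are weak examples of sites that differ. Of all lost peaks, 32.1% overlapped the sgCtrl vehicle list (30.1 to 34.2) and 11.3% the sgCHD1 vehicle list (9.95 to 12.8). Of the sgCtrl DHT peaks shared with sgCHD1 DHT, 85.5% and 70.7% did. Shared peaks had a median width ratio of 1.53 over 18235 matched peaks, with 90.8% wider in sgCHD1 cells (90.4 to 91.2). The lost count was 7683 with a 50% reciprocal overlap. With the same number of the widest peaks taken from every list, gained and lost counts were close to equal in all 4 comparisons, which equal lengths impose.

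Regions closed in both vehicle lists and open in both DHT lists numbered 2102. They made up 62.6% of the 3359 regions that the sgCtrl DHT list held among those closed in both vehicle lists (60.9 to 64.2). Of the 23652 that the sgCHD1 DHT list held there, they made up 8.89%. Both shares lay below those over all peaks. Of all sgCtrl DHT peaks, 90.4% overlapped the longer sgCHD1 DHT list, and of all sgCHD1 DHT peaks, 28.2% overlapped the sgCtrl DHT list. The widest of the 2102 regions were chr21:45349100-45349887 (788 bp), chr4:1901315-1902035 (721 bp) and chr19:37568900-37569606 (707 bp). The opposite set, open in both vehicle lists alone, held 1180 regions, among them chr1:182150179-182150780 (602 bp) and chr10:34811255-34811774 (520 bp). By genotype, 3490 regions were open in both sgCHD1 lists alone, such as chr19:58838272-58839144 (873 bp) and chr3:101497896-101498742 (847 bp). The sgCtrl lists alone shared 463 regions, such as chr19:40731691-40732092 (402 bp) and chr15:66775443-66775820 (378 bp).

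Along the chromosomes, the share of peaks on chromosomes 4 and 6 was higher in sgCHD1 cells under both treatments. Chromosome 6 held 5.57% of sgCtrl vehicle peaks (5.37 to 5.77) and 6.22% of sgCHD1 vehicle peaks (5.96 to 6.49). Under DHT it held 4.91% (4.63 to 5.22) and 6.54% (6.35 to 6.73), respectively. Within chromosome 4 the excess was delimited from 100 to 190 Mb, where the log2 ratio of shares, sgCHD1 over sgCtrl, was 0.30 under vehicle (counting SE 0.064) and 0.53 under DHT (SE 0.076); the latter was 0.25 with equal numbers of the widest peaks. Within chromosome 6 it was delimited from 0 to 110 Mb, at 0.25 (SE 0.054) and 0.56 (SE 0.066). Averaged over treatments, the ratio there fell from 0.28 at 100 to 110 Mb to 0.046 at 110 to 120 Mb. Beyond 110 Mb, 5 of the 6 windows still lay above 0, with a median of 0.084 against 0.36 inside. The highest of them reached 0.29, as high as the lower windows inside, but was at -0.031 under vehicle and 0.62 under DHT. Both segments were drawn after the window profile had been seen, so their ratios are biased upward by the choice.

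**Figure D3:**
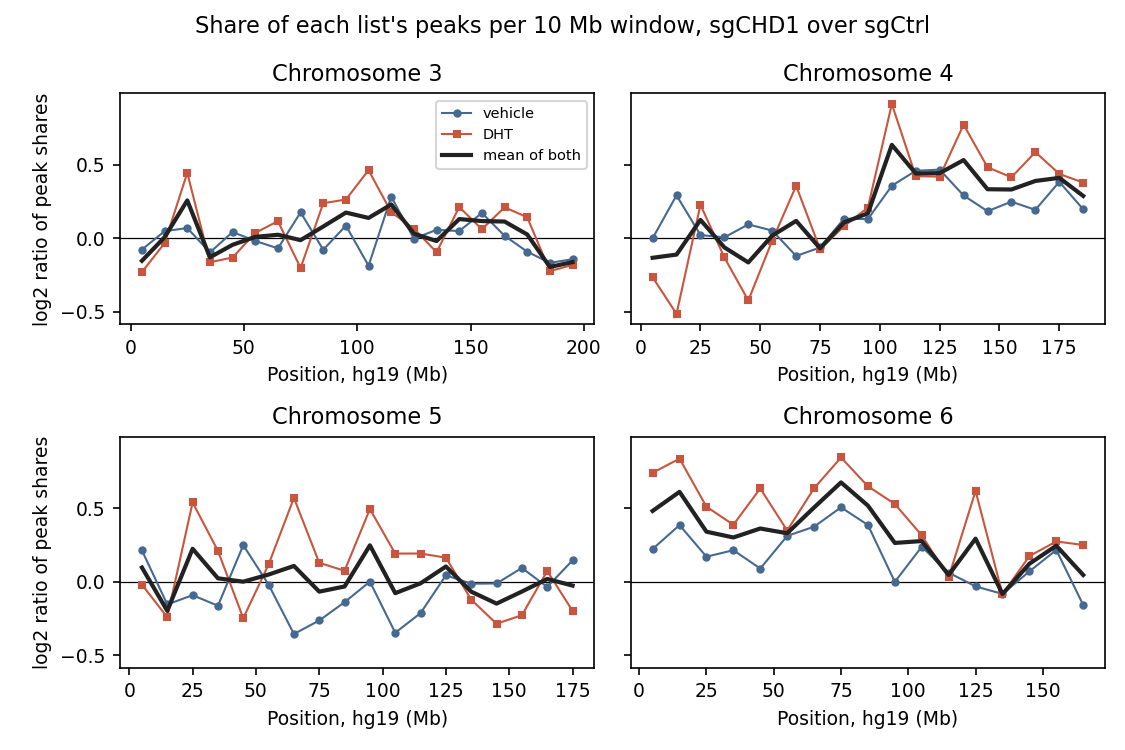
Log2 ratio of peak shares, sgCHD1 over sgCtrl (vertical axis), per 10 Mb window along chromosomes 3 to 6 (horizontal axis, hg19 position in Mb), under vehicle (circles), under DHT (squares) and as their mean (thick line). The mean lies above 0 in the 9 windows from 100 to 190 Mb of chromosome 4 and the 11 from 0 to 110 Mb of chromosome 6, which were chosen for it, and in 5 of the other 6 windows of chromosome 6; chromosomes 3 and 5 are drawn for comparison.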

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

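Each contrast below went opposite ways in the 2 groups it was measured in; with 1 merged list per group, none of these differences was tested. The tests of detection sensitivity and of swapped lists were chosen after the lists were seen.

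The number of peaks was lower with DHT in sgCtrl cells and higher with DHT in sgCHD1 cells, a difference of 2.34 on the log2 scale that the sgCHD1 contrast, lower under vehicle and higher under DHT, shares. A swap of vehicle and DHT lists within 1 genotype would give opposite directions. It would also make the pairs labelled as crossed the ones that share a treatment. Of the crossed pairs, sgCtrl vehicle and sgCHD1 DHT, the longest lists, alone held 11096 regions, and the other pair 61. The product of the treatment-matched counts was 3.66 times that of the crossed ones, and 2.02 times with equal numbers of the widest peaks. This argues against a swap only as far as width stands in for signal and the cut lists are alike in sensitivity, which was not secured. A candidate explanation is that the lists differ in detection sensitivity, through depth, signal over background or threshold; peaks that both lists hold should then be wider in the longer list, and 79.4%, 74.3%, 54.9% and 91.2% of those of unequal width were, in the order of the comparisons in the report, each with an interval above 50%. Shared peaks were wider than exclusive ones in the longer and the shorter lists alike (area under the curve 0.698 to 0.782, peak centres within 250 bp), so that measure does not tell which list was less sensitive. A change in accessibility across most sites would give the same widths, so a biological effect of CHD1 on the DHT response stays open and untested here.

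Median peak width was lower with DHT in sgCtrl cells (180 to 167 bp) and higher in sgCHD1 cells (200 to 207 bp), a log2 difference of 0.16. The share of peaks on chromosome 6 was lower with DHT in sgCtrl cells (5.57% to 4.91%) and higher in sgCHD1 cells (6.22% to 6.54%), a log2 difference of 0.25. The intervals of the sgCHD1 shares overlapped (5.96 to 6.49 and 6.35 to 6.73). Some chromosomes not flagged here also went opposite ways, such as chromosome 13, with log2 share ratios of -0.18 in sgCtrl and 0.27 in sgCHD1 cells. Chromosome 16 held 3.10% and 3.63% of peaks in sgCtrl cells under vehicle and DHT, and 3.46% and 2.92% in sgCHD1 cells, a log2 difference of -0.47 for either contrast. Chromosome 19 held 2.49% and 2.94% in sgCtrl cells, and 2.83% and 2.31% in sgCHD1 cells, a log2 difference of -0.53 for either contrast. On both chromosomes the share was higher in the shorter list of each pair.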

How the results depend on the processing

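Of 90 alternative values, 79 stayed within 1.5 times the reported count or within a segment ratio's counting interval, 11 moved further and 0 of the segment ratios changed sign. Nearest to that bound, peaks lost in sgCHD1 cells under DHT numbered 1310 with a common minimum width, against 1960, and peaks gained in sgCHD1 cells under vehicle 10344 with a 50% reciprocal overlap, against 7041. The widest-peak, minimum-width and dense-cluster settings, and all alternatives for the chromosome segments, were added after seeing the data. With a 50% reciprocal overlap, DHT-gained peaks in sgCtrl cells numbered 7593, DHT-lost peaks in sgCHD1 cells 8712, and peaks lost in sgCHD1 cells under DHT 7683; the stricter rule counts partly overlapping peaks as unshared. With the 20519 widest peaks of each list, gained and lost counts were 9011 and 9099 for DHT in sgCtrl cells, 8300 and 8265 for DHT in sgCHD1 cells, and 9604 and 9458 for sgCHD1 under DHT. For sgCHD1 under vehicle they were 7434 and 7414, so that the balance, 7041 gained and 25440 lost with all peaks, turned. Lists of equal length force gained and lost counts together, so this setting tests no net direction. In it the chromosome 4 segment's log2 ratio under DHT was 0.25; the cause was not tested. Under the other settings for which gained and lost peaks were counted, each comparison had more gained or more lost peaks in the same direction as reported. The lists kept the same order of length in those settings. Unequal lengths largely set the direction, so this sameness is no separate check of it.

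No paired analysis was possible because the duplicates were merged into 1 list per group, so a replicate block and leaving out a replicate were not computable. Score thresholds, top-scoring peaks, promoter distances, gene windows and motif windows were not run, for lack of a score or an hg19 reference used here. Depth is unknown, so how far it limits the shorter lists was not measured.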

Other observations

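The cluster rule, the segments and the tests below were chosen after the data were seen, except the width test on the chromosome 4 and 6 segments, which was written before its result.

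Some changes fell together in clusters of neighbouring regions; the first 4 named here are among those with the largest net change in a comparison. At chr7:89810100-89891976, 11 regions were open in sgCtrl vehicle, 4 in sgCtrl DHT, 6 in sgCHD1 vehicle and 17 in sgCHD1 DHT. At chr1:224464707-224521343 the counts, in the same order, were 5, 0, 3 and 13, and at chr5:107587191-107658631 they were 12, 4, 4 and 15. At chr17:35627604-35658516 they were 8, 1, 0 and 7. The whole lists held 50260, 20519, 31734 and 65463 peaks in the same order. Counts that roughly follow these lengths, as in the clusters on chromosomes 5 and 7, show no change particular to the cluster. The clusters were picked for a large net change and were not tested against list length. Among dense clusters near centromeres, chr16:46385916-46456128 had 36, 32, 28 and 29 open regions and chr10:42355976-42409396 had 34, 32, 28 and 29, while chr21:10765839-10815937 had 8, 8, 8 and 4.

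The 2102 regions open in both DHT lists alone are a candidate set of DHT-opened sites common to both genotypes. The corresponding sgCtrl DHT peaks numbered 2185, and 2148 without dense clusters and chromosomes Y and M, so few of them lay in dense clusters, those near centromeres included. That setting took the whole sgCtrl DHT list only from 20519 to 19878 peaks. It could not have removed most of the 2185, so the small change is no test of the set. Between lists of like sensitivity, sensitivity alone would make regions confined to the 2 treatment-matched pairs of lists as frequent as those confined to the 2 crossed pairs, in which genotype and treatment both differ. With equal numbers of the widest peaks, which takes width as a stand-in for signal, the product of the matched counts over that of the crossed counts was 2.02 rather than 1 (95% interval 1.81 to 2.25). It was 1.54 (1.37 to 1.72) for pairs matched by genotype. The cut kept the sgCtrl DHT list whole, down to 96 bp. It kept sgCtrl vehicle peaks down to 201 bp, sgCHD1 vehicle to 170 bp and sgCHD1 DHT to 265 bp. The cut lists may thus still differ in sensitivity, so a value of 1 is not secured and unequal sensitivity is not excluded. Libraries handled together by treatment could give the same pattern, and the labels name no batch, so a shared response to DHT remains a hypothesis.

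On the segments of chromosomes 4 and 6 the ratio of peak shares, sgCHD1 over sgCtrl, was high by choice of the segments, so runs of 10 adjoining windows were chosen in one treatment and read in the other, which shares no list with it. The 2 highest runs lay on chromosomes 4 and 6 either way, and their log2 ratios in the other treatment were at least 0.25 (counting SE 0.057 for that lowest case). This argues against list length as the only source, since the sgCHD1 list was the shorter under vehicle and the longer under DHT. The next runs, on chromosomes 11 and 13, turned to -0.16 in both cases. On the chromosome 4 and 6 segments, the log2 ratios of DHT over vehicle were -0.13 (SE 0.081) and -0.24 (SE 0.070) in sgCtrl cells. In sgCHD1 cells they were 0.097 (SE 0.058) and 0.078 (SE 0.050). The share was thus higher in the longer list of each genotype, so list length may add to the larger ratios under DHT. With peaks of a list within 12.5 kb counted once, the lowest was 0.20 (SE 0.065), which argues against a few dense clusters; with equal numbers of the widest peaks the chromosome 4 segment under DHT was at 0.25 instead of 0.53. A copy-number difference between the cell lines predicts that shared peaks, too, are relatively wider on the segments in sgCHD1 cells. They were in all 4 cases, by at least 0.047 on the log2 scale (interval 0.0027 to 0.10 for that lowest case). The segments were drawn from the peak numbers of these same lists, and widths were not read in the runs chosen in the other treatment. Higher local signal could raise number and width together, so the widths are no independent support. A gain of these segments in sgCHD1 cells, or a loss in sgCtrl cells, may explain the pattern. So may a broad change in accessibility, which was not tested apart from it.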
